A study of Rattus norvegicus with 3 samples.

How the data were processed

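Dor (Tp53inp2), a protein known for roles in autophagy and as a nuclear receptor coactivator, was profiled by CUT&Tag, in which an antibody tethers a transposase to chromatin so that DNA near the bound protein is cut and sequenced. The samples were rat oligodendrocyte precursor cells (OPC), immature oligodendrocytes (iOL, labelled D1) and mature oligodendrocytes (mOL, labelled D3), with 1 library per stage. Per the labels' protocols, the precursors came from mixed glial cultures, were grown with PDGF-AA at 10 ng/ml and bFGF at 20 ng/ml, and were differentiated with the thyroid hormone T3 at 15 nM and CNTF at 10 ng/ml. Libraries were sequenced as paired-end reads of 150 bp, per the labels' protocols.

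The analysis started from 1 peak list per library. The submitters' processing notes name Bowtie2 2.4.4, deepTools 3.5.1, MACS2 2.2.7.1 and the rat build rn5, without saying what each was used for. The layout of the deposited lists is the narrowPeak format that MACS2 writes. The peak names hold the word pool. What was pooled, whether a control library entered the peak calling and how duplicate fragments were treated are not given in the sources used here. No control library was analysed here, so signal that an untargeted antibody would also give was not subtracted.

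Each deposited row gives a peak's start, end and summit. The authors' fold enrichment is a linear ratio of the fragment pileup at the summit to the local background. The authors' p and q are on the −log10 scale, and no deposited peak had a −log10 p under 5. The deposited score equalled the −log10 p times 10 without its decimals in 99.992% of OPC, 99.995% of iOL and 99.989% of mOL rows. These values belong to each peak in its own list, and the lists differ in length, so a rank in 1 list was never set against a rank in another. Coordinates are given on rn5 and counted from 1.

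The summit pileup and the background were recovered from the deposited fold and p, since MACS2 adds a pseudocount of 1 to both and takes p from a Poisson distribution. A whole-number pileup within 0.001 was found for 100% of the peaks in each list. In simulated peaks with the backgrounds of the 3 libraries, 100% of 1951 OPC, 1989 iOL and 1946 mOL pileups were recovered. Of 40 simulated pileups as deep as those of the mitochondrial genome, the largest error was 0.0028%. Strength below means the summit pileup divided by the genome background, the lowest background that MACS2 uses in a library. That background counts mitochondrial fragments too.

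Rows that overlapped were to be merged within a library, and 0 rows overlapped in each of the 3 lists. Peaks were shared if they overlapped by at least 1 base. Each overlap was set beside the mean of 100 random placements, in which a list was moved by a random offset around each sequence, whose length was taken as the end of its last peak. Regions formed by joining overlapping peaks of the 3 lists were put in 7 classes, with 20 random placements. In lists made from each library's own peaks, 100% of those left in place were found, which checks the calculation only. Of those moved at random, 1.49% in OPC, 1.25% in iOL and 3.80% in mOL overlapped a peak by chance. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per stage there was no replicate spread, and no test between stages was made. A difference between lists is a difference between libraries, not shown to be one between stages.

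The alternatives fixed before the data were examined were peaks with a −log10 q of at least 5, peaks with a fold of at least 5, lists shortened to the number of peaks of the shortest list by q, unmerged rows, assembled chromosomes only, an overlap of 50% of both peaks, and 200 bases centred on each summit. The recovery of pileups, classes of strength, thresholds of 20 and 50 times the background, thinning to a lower background (20 draws, keeping p of at most 1e-05), a distance of 500 bases, local shifts by 20000 and 50000 bases, windows of 1 Mb, chromosome densities and the estimates without mitochondrial fragments were chosen after seeing the data. So was the coverage test, which took the lower 95% Poisson limit of a peak's pileup, scaled it by the ratio of the backgrounds and asked whether the other library would call it with a probability of at least 0.99. That limit takes fragments as independent molecules and covers counting error only. The scaling takes signal over background as equal in both libraries. In simulation, thinned calls came to 100.2 (OPC), 99.5 (iOL) and 99.3 (mOL) per 100 predicted. Simulation and prediction used the same binomial thinning and the genome background alone, so this checks the calculation only.

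The plan also held genomic features, genes with promoter peaks and gene lists. These were not run, since an annotation of rn5 was not used here and the gene table at hand is of GRCr8. The rule set for that case was followed: the peaks named are among the 5 of highest fold in each library and the 5 of highest fold in each class found in 1 library. A ranking of the regions found in all 3 libraries by their lowest fold, the named windows and the named differences at iOL regions were added after their values were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.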

Results

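The occupancy of Dor was mapped in rat oligodendrocyte precursor cells (OPC), immature oligodendrocytes (iOL, D1) and mature oligodendrocytes (mOL, D3), to ask where on the genome the protein lies at each stage of differentiation. Each stage had 1 library. The OPC list held 64732 peaks, the iOL list 59681 and the mOL list 166805. The genome background was 1.47 fragments per base in the OPC library, 0.540 in iOL and 1.83 in mOL. The iOL library was therefore the shallowest, and its weakest callable peak, of 6 fragments, stood 11.1 times above its background. The weakest callable OPC peak had 9 fragments, 6.11 times its background, and the weakest mOL peak 10 fragments, 5.47 times its background.

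Dor peaks were most numerous in the mOL library. It held 2.58 times as many peaks as the OPC library and 2.79 times as many as the iOL library. The peaks covered 77.3 Mb in mOL, 29.5 Mb in OPC and 24.7 Mb in iOL. The median width was 397 bases in OPC, 387 in iOL and 401 in mOL, and the median fold over the local background was 5.25, 5.72 and 5.30. Over the genome background, the median peak stood highest in iOL, at 14.8 times from 8 fragments, against 8.82 times from 13 fragments in OPC and 8.75 times from 16 fragments in mOL. The excess of mOL over OPC also stood among strong peaks: 1974 mOL peaks reached 50 times the background, against 878 OPC and 717 iOL peaks. Of these mOL peaks, 95.5% overlapped an OPC peak of any strength, so few of them were sites without an OPC peak. The order of OPC and iOL depended on the threshold and on coverage, as did that of mOL and iOL. There were 1.08 OPC peaks per iOL peak in the full lists and 1.22 at 50 times the background. The value was 0.439 at 20 times the background and 0.441 after thinning to the iOL background. At 20 times the background, mOL had 14067 peaks and iOL 15181, which is 0.927 mOL peaks per iOL peak. With the OPC and mOL pileups thinned to the iOL background, mOL had 1.04 times as many peaks as iOL and 2.36 times as many as OPC. With the estimated mitochondrial fragments left out of the coverage, thinning left an expected 36377 mOL peaks, 0.610 times the iOL number.

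**Figure D1:**
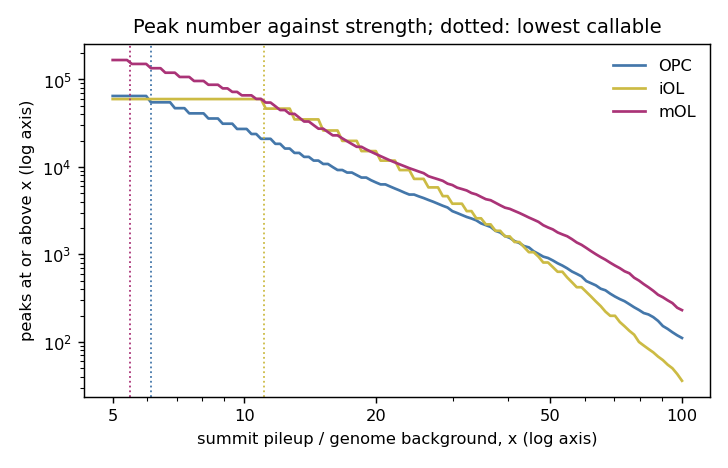
Number of Dor peaks at or above each summit pileup, given as a multiple of the genome background (both axes logarithmic), for the OPC, iOL and mOL libraries. Dotted lines mark the weakest callable peak of each library (6.11, 11.1 and 5.47 times the background). At 50 times the background the mOL line lies at 1974 peaks, above OPC at 878 and iOL at 717.

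A core of 4464 regions carried a Dor peak in all 3 libraries, where random placement gave a mean of 106 (88 to 125 over 20 placements). Most regions lay in 1 library: of 265342 regions, 147277 were found in mOL alone, 48546 in iOL alone and 48467 in OPC alone. Among regions of exactly 2 libraries, OPC and mOL shared 9988 (3386 at random), iOL and mOL 4914 (2982 at random), and OPC and iOL 1686 (1089 at random). Of the mOL peaks, 88.3% overlapped no peak of another library (95% interval 88.1 to 88.4%), against 74.9% of OPC peaks (74.5 to 75.2%) and 81.3% of iOL peaks (81.0 to 81.7%). This order changed with the length of the lists. With the 59681 peaks of lowest q from each library, 46926 OPC, 51348 iOL and 46538 mOL regions lay in 1 library. After thinning to the iOL background, 52395 of the 59681 iOL peaks lay in 1 library, against 51527 of 62237 mOL peaks. Peaks of the shared core were wider, with a median of 720 bases in OPC, 480 in iOL and 853 in mOL, against 387, 384 and 395 for peaks of 1 library. At matched strength the gap was smaller in mOL. At 12 to 15 times the background, mOL peaks had a median width of 550 bases in the core and 426 in 1 library, and at 30 to 50 times 882 and 588. In OPC the gap was smaller at 12 to 15 times (537 and 408) but not at 30 to 50 times (812 and 470). The iOL medians were 397 and 382 at 12 to 15 times and 516 and 435 at 30 to 50 times. The median fold of core peaks was 8.76 in OPC, 8.18 in iOL and 8.96 in mOL, against 5.08, 5.33 and 5.24 for peaks of 1 library. Requiring an overlap of 50% of both peaks left 2245 regions in all 3 libraries, and 200 bases around each summit left 2145.

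**Figure D2:**
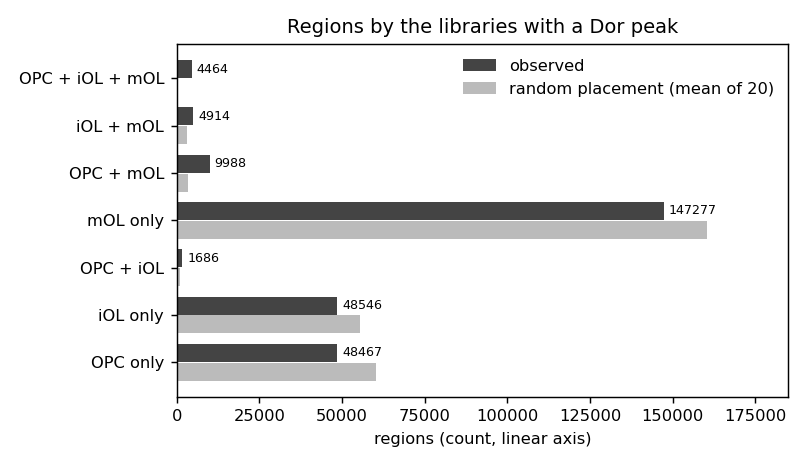
Number of regions (linear axis) with a Dor peak in each combination of the OPC, iOL and mOL libraries, with the mean of 20 random placements in grey. The 4464 regions found in all 3 libraries stand against 106 at random, while each class of 1 library lies below its random value.

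In the pairwise comparisons, 22.4% of OPC peaks were found again in mOL (22.1 to 22.7%), against 5.38% under random placement, and 9.17% in iOL (8.95 to 9.40%), against 1.83%. Of the iOL peaks, 15.6% were found in mOL (5.15% at random) and 9.98% in OPC (2.00% at random). Of the mOL peaks, 8.71% were found in OPC (2.10% at random) and 5.56% in iOL (1.85% at random). Each of the 6 shares lay between 3.01 and 5.01 times its random value. Shifting peaks by 20000 or 50000 bases, which keeps the density of the neighbourhood, gave 2.33 to 7.22% by chance, and the observed shares were 2.38 to 3.87 times these values.

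Sharing rose steeply with the strength of the peak. Of the 878 OPC peaks of at least 50 times the background, 98.5% were found in mOL (97.48 to 99.2%) and 78.7% in iOL (75.8 to 81.4%). Of the 1974 mOL peaks of that strength, 95.5% were found in OPC (94.5 to 96.4%) and 68.4% in iOL (66.3 to 70.5%), and of the 717 such iOL peaks, 93.6% were found in OPC and 94.8% in mOL. Among OPC peaks under 8 times the background, 7.71% were found in mOL and 2.41% in iOL, against 4.90% and 1.66% at random. At 15 to 20 times the background, 2112 of 4158 OPC peaks were found in mOL (50.8%) and 1781 of 13315 mOL peaks in OPC (13.4%), so the shared numbers were closer than the shares. With lists of equal length, the shares over all strengths were 18.2% of OPC peaks in mOL and 18.2% of mOL peaks in OPC.

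**Figure D3:**
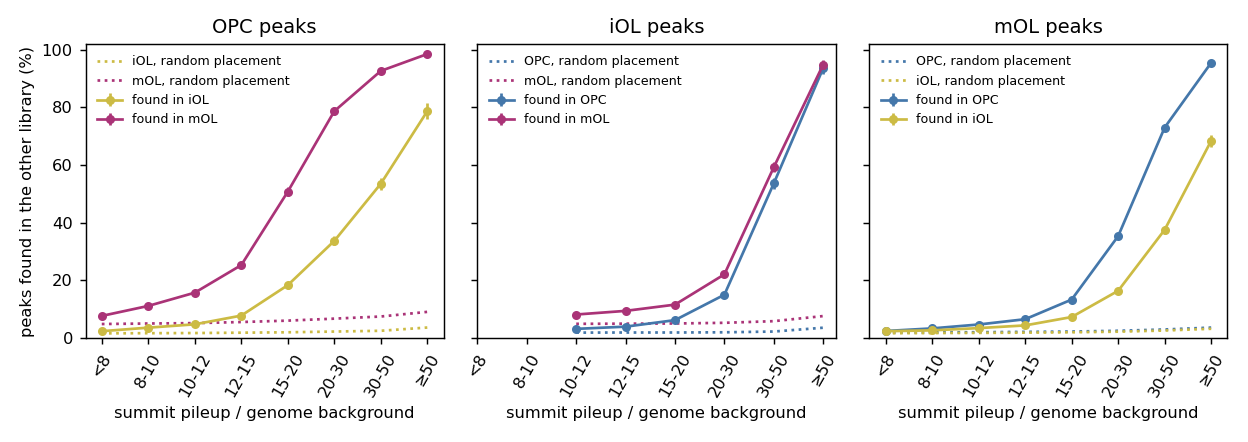
Share of the peaks of each library (percent, with exact 95% intervals) found in each of the other libraries, by summit pileup over the genome background. Dotted lines give the share under random placement. Sharing rises from a few percent for the weakest peaks to 98.5% of OPC peaks in mOL and 95.5% of mOL peaks in OPC at 50 times the background or more.

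Coverage set what each library could show. If fragments were independent molecules and signal over background were equal, the OPC library had the coverage to call 11921 of the mOL peaks. Of these, 5317 had no OPC peak (44.6%, 43.7 to 45.5%). In the other direction, 1314 of 7015 OPC peaks that the mOL library could call had no mOL peak (18.7%, 17.8 to 19.7%). Of 7643 iOL peaks that the OPC library could call, 62.7% had no OPC peak, and of 10348 that the mOL library could call, 62.0% had no mOL peak. Of the peaks that the iOL library could call, 24.7% of 1118 OPC peaks and 36.8% of 2347 mOL peaks had no iOL peak. With mitochondrial fragments left out of the coverage, the mOL share without an OPC peak was 34.3% and the OPC share without an mOL peak was 25.4%. The iOL shares were then 68.5% without an OPC peak and 71.2% without an mOL peak. The shares without an iOL peak were 18.9% in OPC and 26.0% in mOL. These values cover counting error only, since the treatment of duplicate fragments is not given in the sources used here, and peaks too weak for the other library to call say nothing about a difference. At iOL regions of at least 30 times the background called in both, the median mOL to OPC ratio of strength was 1.35. The mOL share without an OPC peak and the OPC share without an mOL peak are therefore not on equal terms.

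Shared regions of high fold over the local background were spread over several chromosomes. The region with the highest minimum fold over the 3 libraries lay on chromosome X at 16414642 to 16414993, with a fold of 20.3 in OPC, 19.9 in iOL and 23.0 in mOL. On chromosome 2 at 217239134 to 217239889, the iOL peak of highest fold had 20.5, and the overlapping peaks had 20.5 in OPC and 19.3 in mOL. The OPC peak of highest fold lay on chromosome 1 at 195137241 to 195137605, with a fold of 22.0, and the same region had 17.7 in iOL and 20.9 in mOL. Over the genome background, that region stood at 76.7 times in OPC, 70.3 times in iOL and 88.0 times in mOL. On chromosome 13 at 72576380 to 72576944, the fold was 21.4 in OPC, 13.5 in iOL and 14.1 in mOL. The strength there was 89.6 times the genome background in OPC, 62.9 times in iOL and 97.3 times in mOL. By strength, mOL thus stood above OPC at this region and at the one on chromosome 1. A region of chromosome 19 at 67047823 to 67048641 carried 894 fragments at its summit in OPC, 178 in iOL and 1197 in mOL, which were 607, 330 and 654 times the background. Its folds were 19.8, 17.9 and 19.2, so a ranking by fold is not a ranking by strength. Genes and features at these positions were not assigned, since an annotation of rn5 was not used here.

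Several of the OPC and mOL peaks of highest fold had no peak in iOL. The mOL peak of highest fold lay on chromosome 14 at 86028400 to 86028755, with 25.1 from 361 fragments, and the overlapping OPC peak had a fold of 16.7 from 149 fragments. The nearest iOL peak was 6065 bases away. On chromosome 15 at 89919331 to 89919735 the fold was 21.7 in OPC and 24.3 in the overlapping mOL peak, and the nearest iOL peak lay 44656 bases away. On chromosome 3 at 18772709 to 18773127, the fold was 23.6 in mOL and 19.0 in OPC, and the nearest iOL peak was 41579 bases away.

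The highest fold among peaks of 1 library lay below that of core peaks: 17.5 against 22.0 in OPC, 18.0 against 20.5 in iOL and 23.5 against 23.8 in mOL. In iOL it lay above the highest fold of peaks shared with 1 other library, 15.9. The highest fold among mOL peaks with no OPC or iOL peak was 23.5, on chromosome 14 at 33958024 to 33958634, from 73 fragments at the summit or 39.9 times the background. The nearest peak was 14294 bases away in OPC and 9267 in iOL. The next ones had folds of 20.6 on chromosome 7 at 91268416 to 91269048, 19.8 on chromosome 4 at 229707545 to 229708203, 18.8 on chromosome 17 at 57054641 to 57055438 and 18.8 on chromosome 9 at 114717169 to 114717678. The last of these lay 899 bases from an iOL peak, and the one on chromosome 17 lay 555 bases from an OPC peak. The highest fold among peaks of OPC alone was 17.5 from 71 fragments, on chromosome 12 at 28263466 to 28263937. An iOL peak lay 648 bases away and the nearest mOL peak 12157 bases away. The highest fold among peaks of iOL alone was 18.0 from 38 fragments, on chromosome 18 at 65241503 to 65242217. The nearest mOL peak lay 4794 bases and the nearest OPC peak 81336 bases away.

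The distribution over chromosomes was alike in the 3 libraries. Chromosome 10 had the highest density of peaks, at 1.42 times the genome mean in OPC, 1.34 in iOL and 1.43 in mOL. Chromosome X had the lowest, at 0.710, 0.751 and 0.746 times the mean, followed by chromosome 4 at 0.773, 0.769 and 0.773. The contrast was larger among peaks of at least 50 times the background, where chromosome 10 stood at 2.86, 2.07 and 2.30 times the mean and chromosome X at 0.194, 0.159 and 0.200 times, the last from 9 OPC, 6 iOL and 21 mOL peaks. Chromosome 12 was also dense in these peaks, at 2.63 times the mean in OPC, 1.58 in iOL and 1.98 in mOL. Across 2911 windows of 1 Mb, the number of peaks correlated between libraries with a Spearman coefficient of 0.779 for OPC and iOL, 0.856 for OPC and mOL and 0.783 for iOL and mOL. These are correlations across windows, which are not independent replicates. The window with the most OPC and iOL peaks lay on chromosome 7 at 12000001 to 13000000, with 75 OPC, 71 iOL and 130 mOL peaks, and that with the most mOL peaks on chromosome 10 at 108000001 to 109000000, with 57, 54 and 141.

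**Figure D4:**
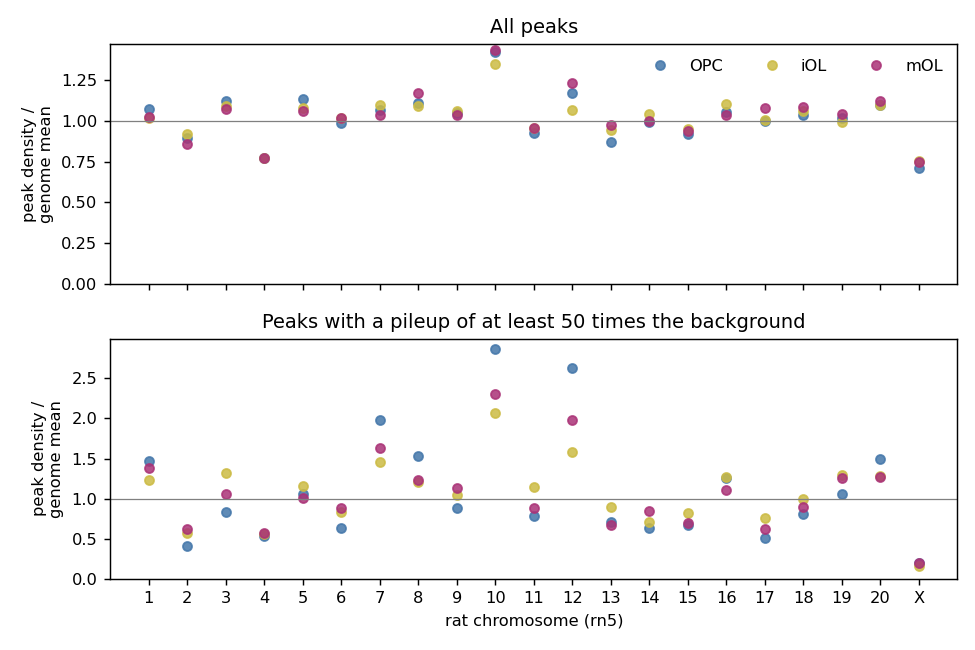
Density of Dor peaks on each rat chromosome divided by the mean over the chromosomes shown, for all peaks (top) and for peaks of at least 50 times the background (bottom), in the OPC, iOL and mOL libraries. Chromosome 10 stands highest for all peaks (1.42, 1.34 and 1.43) and chromosome X lowest for strong peaks (0.194, 0.159 and 0.200).

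Local departures from the common distribution between OPC and mOL were found in single windows. Over all windows, 72.0% of the peaks of the OPC and mOL lists were mOL peaks. Among 2034 windows with at least 60 peaks of these lists, the highest mOL share was 91.3% (82.0 to 96.7%), on chromosome 12 at 35000001 to 36000000, with 6 OPC, 10 iOL and 63 mOL peaks. On chromosome 2 at 164000001 to 165000000 the share was 87.8% (79.6 to 93.5%), with 12 OPC, 29 iOL and 86 mOL peaks. The lowest share was 49.4% (37.9 to 60.9%), also on chromosome 2, at 73000001 to 74000000, with 40 OPC, 22 iOL and 39 mOL peaks. These windows are the extremes of the 2034, and their intervals are not corrected for that choice.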

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

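The thresholds of 20 and 50 times the background, the distance of 500 bases and the thinning were chosen after seeing the data. The alternatives on genomic features, promoter peaks and gene lists were not run, because an annotation of rn5 was not used here. Leaving rows unmerged changed no number of peaks, as 0 rows overlapped, and assembled chromosomes alone moved no count by over 1.5 times. With peaks filtered by q, fold or strength, on assembled chromosomes, or thinned to the iOL background, mOL had 2.11 to 2.85 times as many peaks as OPC. Thinned to the OPC background without mitochondrial fragments, it had 1.90 times as many. In the former settings it had 1.04 to 3.94 times as many peaks as iOL, except at 20 times the background (0.927 times), and thinned to the iOL background without mitochondrial fragments it had 0.610 times as many. Lists of equal length by construction show no such ratio. A −log10 q of at least 5 left 32466 iOL peaks, with 31788 regions in OPC alone and 25283 in iOL alone. A fold of at least 5 left 37119 OPC and 91197 mOL peaks, with 26177 regions in OPC alone and 78739 in mOL alone. Lists of equal length gave 46538 regions in mOL alone, since the mOL list was shortened most. The regions in all 3 libraries fell to 2245 with an overlap of 50% of both peaks and to 2145 with 200 bases at each summit, which are stricter rules of overlap.

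At 20 times the background there were 6660 OPC, 15181 iOL and 14067 mOL peaks, with 2495 regions in all 3 libraries, 1399 in OPC alone, 11407 in iOL alone and 8093 in mOL alone. At 50 times there were 878, 717 and 1974 peaks, with 269 regions in all 3, 195 in OPC alone, 239 in iOL alone and 1157 in mOL alone. Every list was filtered before overlaps were counted, so alone here means that no overlapping peak of another library passed the same filter. Against the full lists, 1885 of the 1974 mOL peaks of at least 50 times overlapped an OPC peak. Likewise, 865 of the 878 OPC peaks overlapped an mOL peak. Thinned to the iOL background, 26347 OPC and 62237 mOL peaks passed (mean of 20 draws), with 17270 regions in OPC alone and 51527 in mOL alone. Over the 10 alternatives that changed the overlap, 4.96 to 40.7% of OPC peaks were found in iOL and 13.0 to 75.03% in mOL, 5.38 to 42.7% of iOL peaks in OPC and 7.21 to 61.8% in mOL, and 5.05 to 35.5% of mOL peaks in OPC and 2.58 to 24.6% in iOL. The 6 shares all fell under the stricter rules of overlap and all rose at 20 and 50 times the background. Coverage limits the iOL library most, as its weakest callable peak, of 6 fragments, stands 11.1 times above its genome background of 0.540 fragments per base. That multiple is the highest of the libraries. No paired analysis was possible because each stage has 1 library.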

Other observations

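The rankings and the mitochondrial values here, and the tests of coverage for peaks of 1 library, of shifted borders in OPC and iOL, and of mitochondrial fragments, were chosen after the results were seen. At regions chosen from the iOL list, some strong Dor peaks differed between the OPC and mOL libraries. Among 644 regions of at least 50 times the background in iOL that were also called in both other libraries, the highest mOL to OPC ratio of pileup over background was 5.91 (95% counting interval 4.75 to 7.42). It lay on chromosome 14 at 46822575 to 46822989, with 93 fragments at the summit in OPC, 40 in iOL and 682 in mOL. The folds over the local background were 21.2 in OPC and 22.6 in mOL, so the recovered local background there was higher in mOL as well. Whether the peak's own fragments entered that background is not given, so a raised neighbourhood is not shown. Folds this close do not show that the pileups were alike. The next highest were 5.39 (2.99 to 10.5) on chromosome 3 at 167088985 to 167089466, with local folds of 5.31 in OPC and 8.48 in mOL, and 4.64 (2.91 to 7.77) on chromosome 2 at 228899896 to 228900679, with 7.05 and 17.0. The lowest was 0.173 (0.0962 to 0.295) on chromosome 7 at 74427296 to 74427787, with 79 fragments in OPC, 29 in iOL and 17 in mOL, and local folds of 16.5 in OPC and 4.89 in mOL. The next lowest was 0.283 (0.174 to 0.448) on chromosome 18 at 28724980 to 28725350, with local folds of 10.7 in OPC and 5.25 in mOL. These are extremes of 644 regions and compare libraries, not stages.

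The mitochondrial genome carried 7 OPC, 8 iOL and 5 mOL peaks of low fold, between 1.18 and 3.04, on a very deep local background. The highest recovered pileup was 179421 fragments in OPC, 77861 in iOL and 125413 in mOL. At the median local background of these peaks, mitochondrial fragments made up an estimated 28.1% of the genome background in OPC (18.1 to 35.9% at the lowest and highest local background), 38% in iOL (21.0 to 44.8%) and 19.4% in mOL (9.52 to 20.3%). The estimate takes the sum of last peak ends, 2900 Mb, as the genome size.

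The mOL list held 2.58 times as many peaks as the OPC list. If fragments were independent molecules, deeper coverage of the mOL library as the whole cause is argued against. Thinned to the OPC background, an expected 142717 mOL peaks still passed, 2.205 times the number of OPC peaks, and 1.90 times with mitochondrial fragments left out. The thinning cannot decide this for coverage in distinct molecules, since stacks of identical fragments would break that independence. A higher signal over background in the mOL library may contribute: at 2140 iOL regions of at least 30 times the background called in both, the median mOL to OPC ratio was 1.35 (quartiles 0.975 and 1.80). With mitochondrial fragments left out of the backgrounds the median was 1.201, between the bounds set for that test, so the share of the excess that comes from fewer mitochondrial fragments in mOL stays open. A change of Dor occupancy with the stage was not tested, since stage and library coincide.

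Most peaks lay in 1 library, and the same element called with shifted borders is argued against as the whole cause, since the share of peaks with no peak of another library went only from 88.3 to 83.0% in mOL, from 74.9 to 66.0% in OPC and from 81.3 to 72.0% in iOL when peaks within 500 bases counted as shared (for OPC and iOL against a bound of 50% set after these values were seen, as they fell short of the 75% set beforehand for mOL). Too little coverage stays open: 44.6% of the mOL peaks that the OPC library could call had no OPC peak (34.3% without mitochondrial fragments). That test takes fragments as independent molecules and signal over background as equal in both libraries. Moreover, 96.5% of the mOL peaks with no OPC peak lay below that coverage. Stacks of identical fragments stay open as well: 30.3% of the mOL, 25.7% of the OPC and 62.3% of the iOL peaks of 1 library had their summit within 2 bases of the middle, as such a stack would. Only iOL passed the 50% set for such stacks, a bound written for mOL. The shape cannot separate stacks from weak peaks, since a peak that is flat at the lowest callable pileup also has it. Among iOL peaks of 1 library, the share was 74.9% under 1.5 times the lowest called pileup and 3.94% at 3 times or more. At 1.5 to 2 times the lowest called pileup, peaks of 1 library had that shape more often than peaks of all 3 libraries. The shares were 54.9 against 16.0% in iOL, 24.5 against 1.45% (of 69 peaks) in mOL and 7.24 against 3.48% in OPC. Peaks of exactly 2 libraries had 45.9% in iOL, 19.5% in mOL and 4.24% in OPC. Under 1.5 times, the gap was smaller in iOL (74.9 against 52.3%) and mOL (51.6 against 41.0%) and larger in OPC (38.5 against 15.8%). At 2 times or more, 20.8% of 6852 iOL and 3.53% of 46030 mOL peaks of 1 library had that shape. Other fragments that overlap part of a stack would move its summit there. Differences between stages and between cultures were not tested, since each stage had 1 library.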
